A study of Danio rerio with 30 samples.

How the data were processed

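The series profiled ribosomes in whole wild-type zebrafish embryos of the TUAB strain at 2, 5, 12, 24 and 48 hpf. Per the labels' protocols, embryos were lysed in cycloheximide, footprints of 28 to 29 nt were gel purified after nuclease digestion, and input RNA from the same lysates was poly-A selected and fragmented. Per the submitters' processing notes the tools were CASAVA 1.8.2, Bowtie2 2.1.0 and TopHat2 2.0.8 with the builds Zv9 and danRer7, and the notes do not say which step used which. The 30 samples were 18 footprint and 12 input runs. Runs of a library counted once, which left 1 footprint and 1 input library per stage, except for 2 column and 2 sucrose footprint libraries at 5 hpf.

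The single deposited table held 957644 ORFs on 54774 transcripts of Ensembl and of 2 further transcript sets, here set A (565 transcripts, names beginning with linc) and set B (1115 transcripts), neither with an annotated coding region. The count values, per the file headers a rate per ORF and stage, were whole numbers of footprint reads that the authors pooled over the libraries of a stage, without normalization. The frame score deposited per ORF and stage was a signed statistic of reads in the 3 reading frames, positive where the ORF's own frame leads and never above 2 times the reads. The coverage fraction, per the file headers, was the share of codons with an in-frame footprint, over the codon number without the stop codon less 2. The input RPKM was computed by the authors per transcript and stage. Other deposited columns gave positions of ORFs and coding regions in nt along the transcript, counted from 1, and no genome coordinates. The table had no values per library, so column and sucrose libraries at 5 hpf were not compared, and whether the 5 hpf column includes the sucrose libraries is not stated. It had no conservation column, so conservation was not analysed here. Gene symbols were paired with 20676 of 31025 gene IDs through the reference table, and symbols are written as that table gives them.

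The unit of analysis was an ORF on 1 representative transcript per gene, chosen as the coding transcript with the longest coding ORF or, without such an ORF, the transcript whose last ORF ends latest (32705 transcripts, 642182 ORFs). The plan counted each genomic location once. As the table gave no coordinates, ORFs with identical length, counts and frame statistics at every stage were taken as 1 location from 20 reads on, a rule devised after the data were seen with a minimum chosen after comparing 3, 10, 20, 50 and 100 reads. This removed 60 copies of coding ORFs and 6233 other copies. ORFs were classed as long coding (over 100 codons), small coding, leader, trailer or non-coding gene ORFs and as ORFs of set A or B, the last 5 classes with at most 100 codons. ORFs that overlap a coding region, lie inside it or share its stop codon were kept apart.

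The frame score used here was the sign of the statistic times log2 of its size plus 1, and the frame index was the statistic over 2 times the reads, computed from 10 reads on, or from 50 reads within a stage, except for muscle and lens genes at 2 hpf, where 10 reads sufficed. The translation threshold was the 5th percentile of the score in long coding ORFs (0.0) with a coverage of at least 10%. Shares were given with Wilson 95% intervals and compared by two-sided Fisher's exact tests over 21 pairs, and medians of score and coverage by two-sided permutation tests with 100000 resamples over 12 pairs, both with Benjamini-Hochberg adjustment.

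For stages, 20110 coding ORFs were used. Footprint counts were divided by ORF length and by the sum of coding reads of the stage to give footprint RPKM, and translational efficiency was footprint over input RPKM, all on the log2 scale with a pseudocount of 1. The input values of sets A and B were on another scale, with medians from 152 to 929 times those of Ensembl transcripts holding the same ORF, and were left out of input and efficiency. A gene was compared when its higher stage had at least 10 RPKM and was said to rise or fall from a log2 change of 2. List medians were set against 10000 random lists matched in 20 bins of mean expression. With 1 pooled value per stage no test across stages was possible. Coding reads per stage ran from 10956057 to 33913444, and 49.4% of coding ORFs at 2 hpf and 83.7% at 48 hpf had at least 10 reads. In an ORF of 1000 nt, 3 reads, used as the floor, equal 0.274, 0.2, 0.0943, 0.12 and 0.0885 RPKM at the successive stages. PCR reads are not independent molecules, so intervals and floors cover counting error only.

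Lists of genes, the threshold, the comparisons and the rule for named genes were fixed before the data were examined. The rule named the 8 ORFs of each class with the highest score among passing ORFs of at most 100 codons, the 3 small coding ORFs with the lowest score among those with at least 100 reads, the 10 largest rises and falls of each step, up to 4 members per list with the highest value, and apela, pln, sln, mrln and tmsb4x. Alternatives tried were other ORF units, densities, lengths, thresholds and coverage minimums, other pseudocounts, no floor, and scaling to an equal median coding ORF, together with alternatives added after the data were seen.

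Methods were tested on simulated data. For each step, 200 genes of 20110 with 8-fold changes were planted at the observed depths, 100% were recovered, and 0 other genes passed. Both stages were drawn as Poisson counts from the same means, and changes were planted only in genes above the floor. Variation between libraries or embryos was not simulated, so these figures are not error rates of the stage comparisons. Of 100 planted lists with a 4-fold change 100% were called from 24 to 48 hpf, together with 12 of 100 unchanged lists, and in a larger run of 1000 unchanged lists per step 49, 43, 61 and 47 were called. Of 200 simulated class pairs with a 3-fold difference in share 100% reached 0.05, and 5 of 200 without a difference did. Of 200 permutation tests without a difference 9 reached 0.05, and the frame statistic lay within the set tolerance of its expected value in 97.8% of 1000 simulated ORFs. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, with fixed random seeds.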

Results

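Ribosome footprints and poly-A selected input RNA were sequenced from whole wild-type zebrafish embryos at 5 stages, 2, 5, 12, 24 and 48 hours post fertilisation (hpf). Of the 30 samples, 18 held footprints and 12 held input RNA, and several were sequencing runs of the same library. Footprint samples numbered 3 at 2 hpf, 8 at 5 hpf, 3 at 12 hpf, 2 at 24 hpf and 2 at 48 hpf, and only 5 hpf had replicates, 2 after separation on a column and 2 after a sucrose cushion. Input samples numbered 2, 3, 2, 2 and 3 at the same stages. The deposited table held a single pooled value per stage, so no stage value had a replicate and stages were compared by the size of a change, without a test. Annotated coding open reading frames (ORFs) held 10956057 footprint reads at 2 hpf, 15030958 at 5 hpf, 31809619 at 12 hpf, 24903832 at 24 hpf and 33913444 at 48 hpf. In an ORF of 1000 nt, 3 reads corresponded to 0.274 RPKM (reads per kilobase, scaled to the total of coding reads) at 2 hpf and to 0.0885 at 48 hpf. The frame index, which is 1 when all reads lie in the ORF's own frame and 0 when reads are spread evenly, had a median in long coding ORFs of 0.525, 0.708, 0.624, 0.415 and 0.595 at the successive stages. The elongation factor gene eef1a1l1 took 1.2% of the coding reads at 12 hpf, the apolipoprotein B gene apobb.1 took 1.37% at 24 hpf, and the keratin gene krt4 took 1.57% at 48 hpf.

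The title of the series names the identification of small ORFs, which sets the first question, namely in which classes of transcript region ORFs of at most 100 codons carry footprints in their own frame. Among annotated coding ORFs of this size the highest frame scores belonged to apoc1, an apolipoprotein (85 codons, score 16.56), tmsb4x, an actin-binding thymosin (44 codons, 16.44), and hmgn6, a nucleosome-binding protein (93 codons, 16.02). The ribosomal protein genes RPL37 and RPL38, the calcium-binding protein gene icn, the ubiquitin gene ubb and ENSDARG00000042389 followed with scores from 15.88 down to 15.51. In 5' leaders the highest scores were those of gpx4a, a glutathione peroxidase (69 codons, 12.12), the mitochondrial carrier gene UCP2 (35 codons, 11.83) and the actin gene actb1 (39 codons, 11.28), ahead of ENSDARG00000016405, SEPHS2, GPX4, EIF5 and C19H6orf62. Those of gpx4a, SEPHS2 and GPX4 lie in selenoprotein genes, in the frame of the annotated coding region. They may be parts of the annotated proteins. In the actb1 leader ORF only 10.8% of codons carried an in-frame footprint, so its score says little about phasing along the ORF. In 3' trailers an ORF of 49 codons in ENSDARG00000023055 held 40789 reads (score 15.59), and DEPDC7 (12.76), ENSDARG00000059124 (11.77), SLC16A8 (11.48), ENSDARG00000088373, PFN2, ENSDARG00000076892 and EIF1 followed. The score is the signed log2 of the deposited frame statistic and grows with the number of reads.

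Genes annotated as non-coding held small ORFs with high scores as well. The highest scores were those of ENSDARG00000082753 (5 codons, 16.85), si:dkey-151g10.6 (25 codons, 16.42) and ENSDARG00000080337 (34 codons, 13.03), but the frame index of the last was only 0.0324 over 128758 reads. The ORF of ENSDARG00000082753 spans nt 8 to 25, less than a footprint of 28 to 29 nt. Its 79150 reads lie over few codons, so its score says little about phasing. ENSDARG00000095752, si:dkey-53f14.4, the stress-response gene nupr1a (76 codons), ENSDARG00000092212 and STMP1, known as a short mitochondrial membrane protein (46 codons), scored from 11.97 down to 11.46. In transcript set A, whose names begin with linc, linc-wrb (93 codons, 76790 reads) scored 16.70 and linc-mipep1 (87 codons) 16.33, followed by linc-csnk1a1 (13.76), linc-zgc:171223 (13.72), linc-zgc:193613 (13.53), linc-brsk1__(2_of_2), linc-bin2a and linc-mettl3. The ORFs of linc-csnk1a1 and linc-zgc:171223 both have 73 codons and near-equal reads at every stage, such as 7202 and 6800 at 48 hpf. They may be copies and are not certain to be separate findings. In transcript set B, which like set A carries no annotated coding region, Zv9_00054343 (42 codons) scored 10.68, Zv9_00057916 9.97 and Zv9_00000174 8.69. The lowest scores among small coding ORFs with at least 100 reads were those of ENSDARG00000093817 (-15.98 over 55310 reads), si:ch211-134c9.2 (-9.94) and si:ch211-229b6.1 (-9.70).

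An ORF passed when its frame score reached the 5th percentile of long coding ORFs, which was 0.0, and when at least 10% of its codons carried an in-frame footprint. The long coding ORFs included 7.23% without reads, whose score is 0, so the score rule was weak and coverage did most of the filtering. Median lengths were 420 codons in long coding and 82 in small coding ORFs, and 9 to 12 in the other classes. There 1 codon with an in-frame footprint can reach the coverage minimum, so shares of classes that differ in length are not like for like. Of 409 small coding ORFs 274 passed, 67.0% (Wilson 95% interval 62.3 to 71.4%), and of 19701 long coding ORFs 12243 passed, 62.1% (61.5 to 62.8%). In leaders 3730 of 19968 small ORFs passed (18.7%, 18.1 to 19.2%), in trailers 2721 of 224928 (1.21%, 1.17 to 1.26%), and in non-coding genes 1020 of 25105 (4.06%, 3.83 to 4.31%). In set A 253 of 19070 passed (1.33%, 1.17 to 1.5%) and in set B 152 of 17168 (0.885%, 0.756 to 1.04%). Across 21 pairs of classes, tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, leader ORFs passed more often than trailer ORFs (odds ratio 18.8, p too small to be represented), as did ORFs of non-coding genes (odds ratio 3.46, adjusted p = 1.12e-197, raw p = 7.48e-198). Set B passed less often than trailers (Fisher's exact test, odds ratio 0.729, adjusted p = 0.000115, raw p = 0.000104), and neither set A against trailers (higher by 0.117 percentage points, adjusted p = 0.159) nor small against long coding ORFs (odds ratio 1.24, adjusted p = 0.0526, raw p = 0.0501) reached the 0.05 level. Both depended on the minimum of 20 reads for merging identical ORFs, which was chosen after seeing the data. Set A minus trailers reached the level with 3, 10 and 100 reads (0.156, 0.200 and 0.191 points), and small minus long coding with 50 and 100 reads (4.86 and 4.87 points). At single stages small minus long coding reached it at each of the 5, and set A exceeded trailers at 2, 5, 12 and 48 hpf and lay below them at 24 hpf, both with the threshold recomputed there (-3.39) and with 0.0. The threshold of 0.0 let through ORFs with few reads, and at the 25th percentile of long coding ORFs, a score of 6.64, 435 leader ORFs (2.18%), 77 trailer ORFs (0.0342%), 228 ORFs of non-coding genes (0.908%), 49 of set A (0.257%) and 11 of set B (0.0641%) remained. At that threshold set A exceeded trailers (Fisher's exact test, odds ratio 7.52, adjusted p = 3.95e-22), while set B against trailers, now higher, had an adjusted p of 0.0616. ORFs were the unit of these tests, and the intervals and p-values cover counting error only, not variation between embryos.

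**Figure D1:**
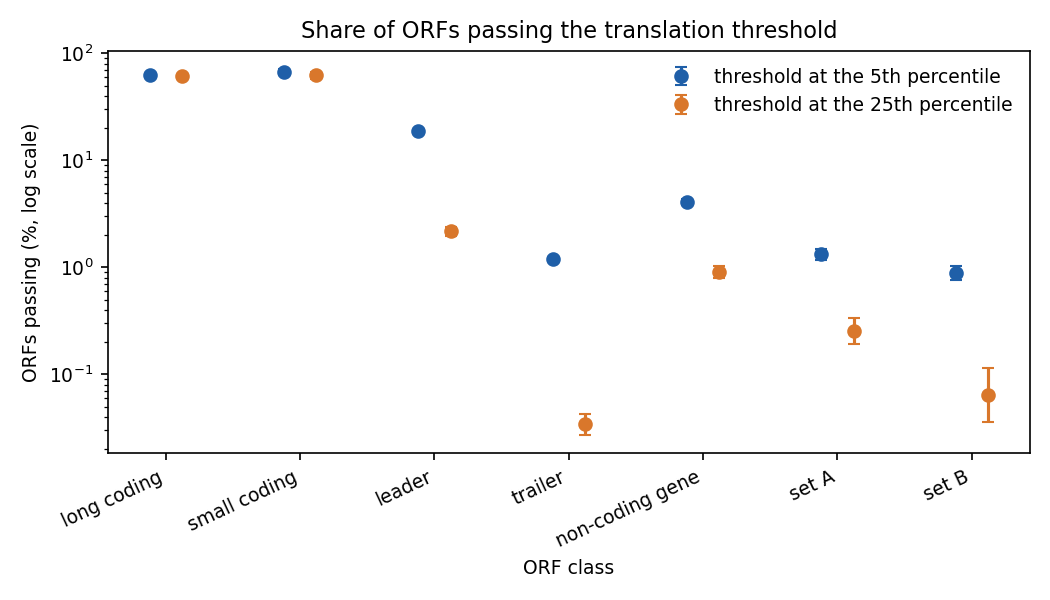
Percent of ORFs that passed (log axis) in 7 ORF classes, at the threshold of 0.0 and at the stricter threshold of 6.64, with Wilson 95% intervals as bars. Long coding ORFs go from 62.1% to 61.7% and small coding ORFs from 67.0% to 62.6%, while leader ORFs go from 18.7% to 2.18% and trailer ORFs from 1.21% to 0.0342%.

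Small coding ORFs had a median score of 8.55 against 9.33 in long coding ORFs (difference -0.78, permutation test, adjusted p = 0.00041) and a median coverage of 40.3% against 17.7% (adjusted p = 1.09e-05, from the smallest p that 100000 permutations can give, 1e-05). Against leaders, trailers, non-coding genes and both further sets, whose median score and coverage were 0, the differences of 8.55 and 40.3 points had the same smallest p. In these classes from 60.2% (leaders) to 93.0% (set B) of ORFs held no reads, so the medians of 0 follow from unread ORFs. These permutation tests therefore do not speak about phasing where reads exist. Among ORFs with at least 10 reads the median frame index was 0.588 in small coding ORFs, 0.557 in long coding ORFs, 0.265 in leaders, -0.271 in trailers, -0.145 in non-coding genes, -0.425 in set A and -0.128 in set B.

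Among the small proteins grouped in advance, 16 of 16 small ribosomal proteins passed, and the 9 of at most 100 codons had a median score of 15.04. Of 21 small respiratory chain subunits 20 passed, among them cox8a and UQCRH, and all 14 Sm and Lsm proteins of the spliceosome passed, among them SNRPD3 and SNRPD2. Of 14 small membrane or secretory proteins 13 passed, including the translocon subunits SEC61B and SEC61G, and TOMM5 did not, with a score of -7.37 over 874 reads. All 13 small chaperone, ubiquitin-like and cell cycle factors passed, among them sumo3a and dynll1. Of 11 small secreted, signalling and actin-binding peptides 7 passed, including tmsb4x and the chemokine gene cxcl12b, while the neuropeptide gene NPY held 1 read and gnrh3 held 31. All 7 histones, all 19 gastrula genes, all 14 muscle genes, all 8 neuronal genes and all 13 epidermis and hatching gland genes passed. The counts were 16 of 19 maternal oocyte genes, 14 of 15 somite genes, 8 of 10 lens crystallins, 5 of 8 globin and erythroid genes and 10 of 18 yolk and liver proteins. Of the long non-coding RNA list no coding ORF was measured, and 1 of its 2 measured non-coding genes held a passing ORF. The genes pln, sln and mrln were not measured.

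The ORF of apela, which encodes the secreted peptide Toddler, spans 58 codons and lies in a gene annotated here as non-coding. It held 1361 reads, a score of 10.75 and a coverage of 82.1%. Its footprints stood at 0 RPKM at 2 hpf, 141 at 5 hpf, 144 at 12 hpf, 31.5 at 24 hpf and 6.5 at 48 hpf, and its input at 0.111, 44.5, 39.9, 6.75 and 0.963 RPKM. Footprints of tmsb4x stood at 104, 226, 2419, 6612 and 5262 RPKM over the same stages, with an input of 16.8, 276, 1063, 4965 and 6379 RPKM. Its 2 hpf value rests on 154 reads. Whether reads of the 48 hpf library, a candidate given below for muscle and lens genes at 2 hpf, are among them was not tested.

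**Figure D2:**
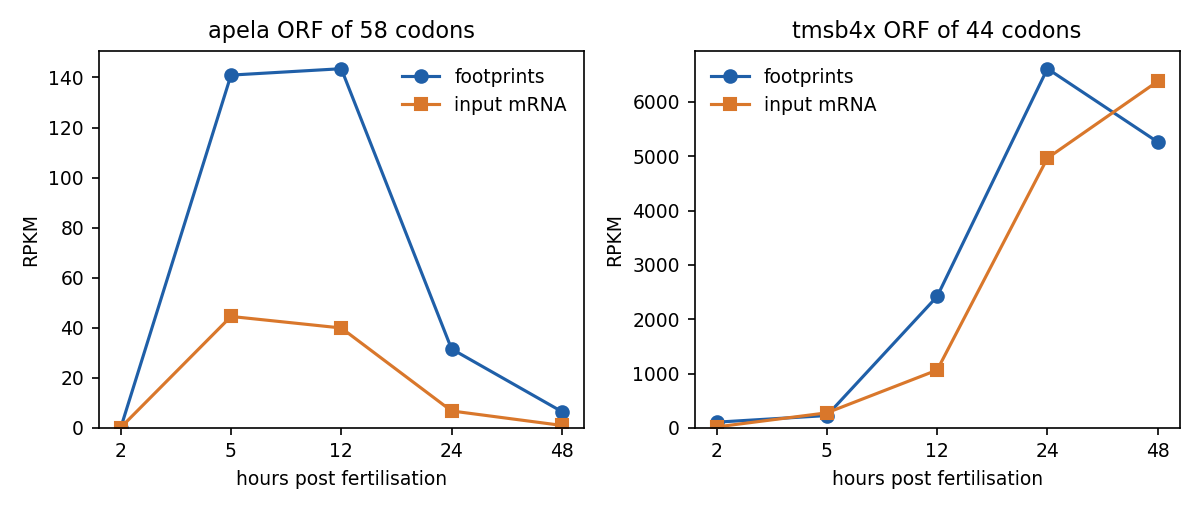
Footprint and input RPKM of the apela and tmsb4x ORFs by stage in hpf, 1 pooled value per point. Footprints of apela are highest at 12 hpf, at 144 RPKM, and those of tmsb4x at 24 hpf, at 6612 RPKM.

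The design names 5 stages, and the second question is which genes gained or lost footprints between successive stages. A gene was said to rise or fall when its log2 change reached 2, a 4-fold difference, after adding 1 RPKM and with at least 10 RPKM in the higher stage, which is a rule of size and not a test. Values were scaled to the total of coding reads, so a gene's change is relative to the total. The median log2 change of footprints above the floor was -0.46, 0.56, -0.24 and -0.32 over the 4 steps, and became -1.54, -1.26, -0.72 and -0.11 when stages were scaled to an equal median coding ORF. For input RNA the medians were -1.39, 0.35, -0.59 and -0.30, and -0.24, -0.51, -0.27 and -0.19 after that scaling. It used the median of all 20110 coding ORFs. Only 49.4% of them at 2 hpf and 57.3% at 5 hpf had at least 10 footprint reads. The footprint scale of these stages therefore rests on ORFs with few reads. A gain that disappears under the scaling is not shown to be absent. Gene lists were set against 10000 random lists matched on expression, and the percentile of the list's median is given. Counts of list members cover those above the floor. A gene near 0 in 1 of the stages can reach the floor in the other only by a change that passes the rule of size.

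**Figure D3:**
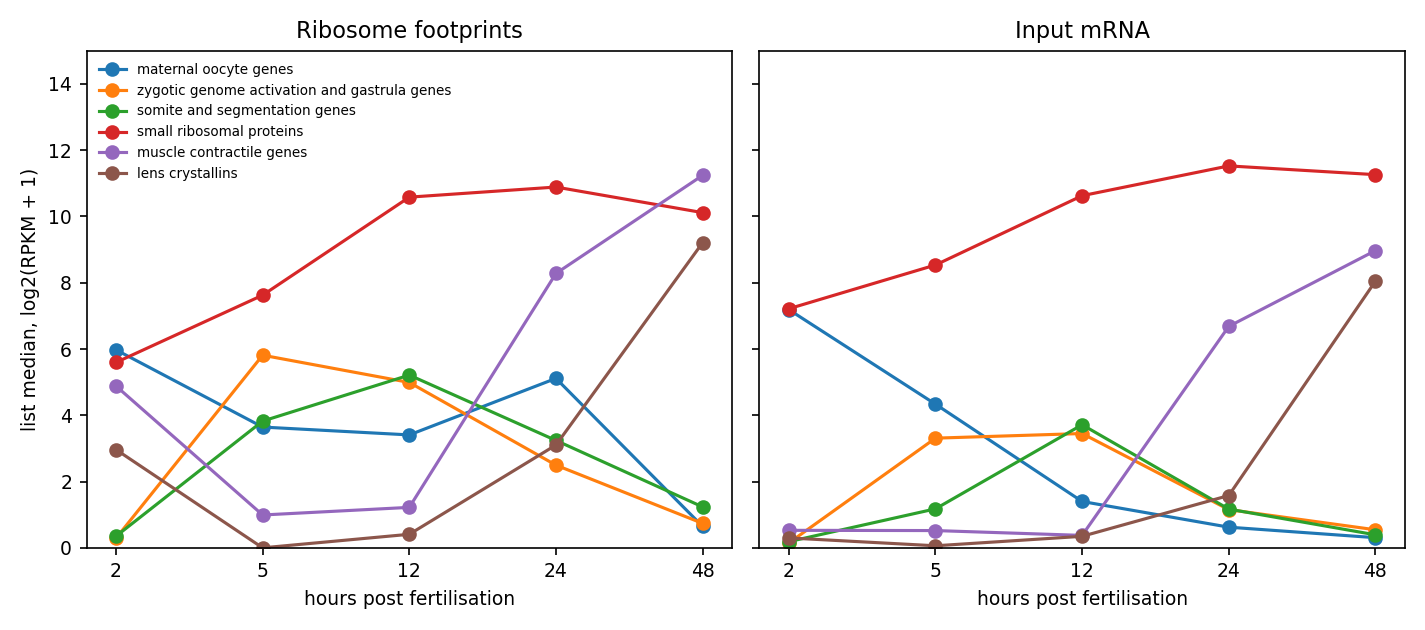
Median footprint (RPF) and input mRNA levels, as log2(RPKM + 1), of 6 gene lists by stage in hpf, with 1 pooled value per stage. The muscle list has a median of 28.5 footprint RPKM at 2 hpf and 2417 at 48 hpf, and the maternal list has 61.9 at 2 hpf and 33.6 at 24 hpf.

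Between 2 and 5 hpf, genes of the early zygotic programme gained footprints while oocyte genes lost them. The mesoderm factor gene tbx16 rose from 0.581 to 579.8 RPKM, mixl1 rose from 0 to 123 RPKM, and SOX3 and klf17 rose by log2 6.83 and 6.53. Of 19 measured gastrula genes 17 were above the floor, and these rose (median 5.49, percentile 100.0), as did 7 of 8 somite genes (4.03), including pcdh8, her7 and her1, and 10 of 16 small ribosomal proteins (2.14, and 1.16 under the equal-median scaling), including RPL29 and RPL30. Of 17 maternal oocyte genes 10 fell (median -3.01), among them cldnd (-6.78), the cyclin gene CCNA1 (-5.14) and the oocyte polarity gene buc (-5.13). The largest rises were those of asb11 (0 to 519.8 RPKM), ENSDARG00000096596, dleu7 (0 to 387 RPKM), tbx16, stm, GADD45B (0 to 287 RPKM), nnr, sult6b1, mid1ip1a and ENSDARG00000094101. The largest falls were those of ENSDARG00000052717 (-8.14), sh2d5 (-7.72), ENSDARG00000001915 (-7.41), cldnd, CTSZ, zgc:56231, MKNK2, pvalb2 (87.4 to 0 RPKM), micall2b and cldng.

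In the same step 4 of 11 epidermis and hatching gland genes rose and 3 fell (median 1.69, percentile 99.4, and 0.69 under scaling), with krt8 at 5.93 and he1.2 at -2.60. All 11 muscle genes (median -3.85), all 4 lens crystallins (-4.30) and all 3 globin genes (-5.12) fell, from levels such as 49.5 RPKM for the parvalbumin gene pvalb1 and 18.2 for CRYBB1. The median input of the muscle, lens and globin lists at 2 hpf was 0.442, 0.230 and 0.431 RPKM. That of the epidermis and hatching gland list was 0.767 RPKM, against median footprints of 29.0 RPKM. Medians of the respiratory chain (0.47), Sm and Lsm (0.49), membrane (0.33), chaperone (0.02), histone (0.60) and yolk (0.72) lists lay within the random range, and under the scaling to an equal median they turned to -0.29, -0.51, -0.56, -0.88, -0.80 and -0.28. With members at 0 reads set to 3 reads, the medians were 6.45 for gastrula genes, 4.54 for somite genes and -5.70 for crystallins. In all, 1199 of 6940 genes rose and 1529 fell, so 44.0% of the genes that moved had risen, against 24.0% after scaling. Input RNA was below 1 RPKM in the higher stage for 80 of the rises and 58 of the falls.

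Between 5 and 12 hpf, genes of yolk, liver, epidermis and hatching gland gained footprints. The intestinal fatty-acid binding protein gene FABP2 rose from 2.00 to 1738 RPKM and apoa2 from 3.90 to 801 RPKM, and 8 of 10 yolk and liver genes rose (median 5.27, percentile 100.0), including tfa, the transferrin gene. Of 11 epidermis and hatching gland genes 10 rose (median 3.14), with the cathepsin gene ctslb at 6.86 and the hatching enzyme genes he1.2 and he1.1 at 6.27 and 6.15, and ctslb is counted in the yolk list as well. All 16 small ribosomal proteins rose (median 2.77, percentile 99.9), with RPL39 at 4.15, as did 8 of 18 respiratory chain subunits (1.93) and 7 of 13 somite genes (2.22), among them the myogenic factor genes MYF5 (5.65) and MYOD1 (0 to 61.5 RPKM). Under scaling the medians became 3.69 for yolk and liver, 1.55 for epidermis, 1.18 for ribosomal, 0.34 for respiratory chain and 0.66 for somite genes, so the last pair lost most of its gain. Gastrula genes divided, as 6 of 19 fell and 3 rose (median -0.91, percentile 0.05, and -2.46 under scaling), with mixl1 at -6.33 and tbx6 at 5.03.

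Other large rises were those of txnb (0 to 457 RPKM), MDK (0 to 331 RPKM), ENSDARG00000040574, GAMT, apobb.1, pvalb9, a2ml and DAO. The largest falls were those of ENSDARG00000096596 (-8.72), nnr (-6.39), mixl1, ENSDARG00000009737, mxtx2 (66.3 to 0 RPKM), pnp4a, sebox (57.4 to 0 RPKM), ENSDARG00000061123, pou5f3 (-5.70) and ENSDARG00000041341. The secreted peptide list (3.41, 3 genes), membrane list (1.57) and maternal list (-1.03) also lay outside the central 95% of random lists. They became 1.82, 0.01 and -2.65 under the equal-median scaling, so the gain of the membrane list depends on the scaling. The Sm and Lsm (0.77) and chaperone (0.44) medians did not and turned to -0.82 and -1.17 under scaling, and those of histones (-0.65) and neuronal genes (2.35) lay within the range as well. In all, 1361 of 7092 genes rose and 373 fell, so 78.5% of those that moved had risen, against 17.3% after scaling. In 26 genes with at least 50 RPKM of input at 2 hpf and below 1 RPKM at 24 and 48 hpf, a group chosen after its values were seen, the density of trailer reads at 12 hpf was 61.9% of that of the coding ORF, against 0 in the median of other genes.

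Between 12 and 24 hpf, muscle and blood genes gained footprints. All 13 muscle genes rose (median 6.78, percentile 100.0), among them the creatine kinase genes ckmb (8.01) and ckma (7.37), the calcium pump gene atp2a1 (7.88) and the myosin gene myhz1.1 (7.18). All 4 globin and erythroid genes rose (6.75), with the embryonic globin gene hbbe3 at 8.37, although the hbae1 copies are near-identical and their reads cannot be assigned to 1 copy. Of 13 epidermis genes 6 rose (1.59), including he1.3 and icn, and 8 of 12 somite genes fell (-2.71), including msgn1 (-3.60), her7 (-3.13) and tbx6 (-2.96), as did 6 of 15 gastrula genes (-1.55), including cdx4 (-3.93). Of 16 maternal oocyte genes 10 rose (2.16, percentile 100.0), with buc going from 9.61 to 56.1 RPKM and org from 32.7 to 179 RPKM, while their input at 24 hpf was 0.123 and 0.332 RPKM.

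The further large rises were 2 ORFs named MYL1, MYL11, myhz1.3 and the collagen gene col1a1a, and the largest falls were rbp7a (82.1 to 0 RPKM), zgc:112994 (-5.77), cyp2x6, pmaip1, GNGT2, krt99 (-4.86), six7, ANKRD37, ifi27.1 and si:ch211-165f21.6. Medians of the ribosomal (0.40), secreted (1.24) and neuronal (1.63) lists stood above the random range. They became 0.02, 1.07 and 0.86 under scaling, so the gain of the ribosomal list depends on the scaling. The median of the respiratory chain list (0.26) stood above the random range too but turned to -0.12. Sm and Lsm (-0.67), membrane (-0.44), chaperone (-0.50) and histone (-0.02) medians did not stand out, nor did that of yolk genes (0.03, and -0.35 under scaling). In all, 562 of 7569 genes rose and 227 fell, so 71.2% of those that moved had risen, against 48.6% after scaling. Input RNA was below 1 RPKM in the higher stage for 88 of the rises and 11 of the falls. In the 44 genes with at least 500 reads at 2 hpf and input that was at least 50 RPKM then but below 1 RPKM at 24 and 48 hpf, the median frame index at 24 hpf was -0.0046, against 0.416 in other long coding ORFs. From 12 to 48 hpf, without 24 hpf, 959 genes rose and 703 fell.

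Between 24 and 48 hpf, footprint reads of lens genes increased and those of the oocyte genes decreased. All 8 lens crystallins rose (median 5.67, percentile 100.0), among them cryba1b from 8.41 to 594 RPKM, and 9 of 14 muscle genes rose (2.67), including the parvalbumin genes pvalb1 (5.57), pvalb2 (4.11) and pvalb3 (3.44). Of 8 neuronal genes 3 rose (1.75), namely GNG3, DPYSL3 and ELAVL4, and of 4 globin and erythroid genes 2 rose (1.69). Of 15 maternal oocyte genes 14 fell (-4.88), with cldnd at -6.19, CCNA1 at -5.58 and buc at -5.45, and the hatching enzyme gene he1.3 fell from 87.4 to 0.434 RPKM. In the maternal groups chosen after their values were seen, the 24 hpf reads from which such falls start had a median frame index of -0.0046 in 44 genes and a trailer density of 70.7% of the coding ORF in 26. The largest rises, crygm2d15 (8.75), crygm2f, crygm2d10, ENSDARG00000088687, ENSDARG00000076693, crygm2d16, crygm2d14, crygm2d20, crygm2d4 and crygm2d13, belong mostly to a crystallin cluster of near-identical copies, so the share of each copy is uncertain.

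The other large falls were those of cldng, ENSDARG00000001915 (-5.81), ENSDARG00000089516, ppt2a.3, ENSDARG00000087860, PPT2 and ENSDARG00000091430. Lists below the random range were ribosomal proteins (-0.74), Sm and Lsm proteins (-0.67), gastrula genes (-1.08), yolk genes (-0.74) and somite genes (-1.67, but 0.46 under scaling, over the genes then above the floor), and epidermis genes (0.41) lay above it. Medians of the respiratory chain (0.10), secreted (-0.33), membrane (-0.31), chaperone (-0.14, and 0.01 under scaling) and histone (-0.36) lists did not stand out. In all, 332 of 7264 genes rose and 270 fell, and 91 of the falls were genes with input below 1 RPKM at 24 hpf. With at least 1 RPKM of input required, 179 genes fell.

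Input RNA addressed the same steps at the level of the message. Between 2 and 5 hpf 9 of 19 measured gastrula genes (median 4.05), including the receptor gene aplnrb (5.51), 6 of 13 epidermis genes (4.30) and 4 of 18 yolk genes (4.86) were above the floor. All of these rose, which the floor favours in genes near 0 at 2 hpf. Of 19 maternal genes 6 fell (-1.27), with the deadenylation regulator gene BTG4 at -6.03 and buc at -4.97. The largest rises after ENSDARG00000096498 (8.38) were 9 ORFs of 103 codons with near-equal values, such as ENSDARG00000090893 (7.29) and ENSDARG00000091313 (7.06), whose reads cannot be assigned to 1 copy, and the largest falls began with rasef2 (-6.04) and BTG4 and included si:ch211-167j6.3, trim35-29 and sinup. Between 5 and 12 hpf all 11 epidermis genes (4.32), all 9 yolk genes (5.21) and 6 of 8 somite genes (3.76) rose and 11 of 13 maternal genes fell (-2.86), led by cldnd (-8.30). FABP2 (0 to 303 RPKM), FABP1 (7.12) and a cathepsin-like family including zgc:174855, whose copies are near-identical, had the largest rises, and znf106b (-7.66) and zglp1 (-7.11) fell. Between 12 and 24 hpf all 13 muscle genes (5.76), all 3 globin genes (7.02) and all 3 lens crystallins above the floor (3.82) rose, and cdx4 (-4.99), hp (-4.74), msgn1 (-4.67), krt99 and HSPB1 fell. Between 24 and 48 hpf all 7 crystallins (4.44) and 6 of 13 muscle genes (1.95) rose, while ctss2.1 (-4.12), ctsll (-3.15) and he1.3 (-3.13) fell.

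Of the genes measured in input RNA, 539 of 6140 rose and 2039 fell between 2 and 5 hpf, 698 of 4140 rose and 673 fell to 12 hpf, 159 of 3583 rose and 165 fell to 24 hpf, and 120 of 2759 rose and 30 fell to 48 hpf. The percent of moved genes that had risen was 20.9, 50.9, 49.1 and 80 over the steps, against 55.2, 30.7, 64.5 and 83.6 after scaling. Of the lists, input of Sm and Lsm (-0.86), membrane (-0.84) and chaperone (-0.58) genes at the first step turned to 0.09, 0.11 and 0.36 under scaling, and that of histones at the second from 0.35 to -0.23. Across genes, which are not independent replicates, footprint and input changes had a Pearson correlation of 0.546, 0.681, 0.841 and 0.902 over the steps.

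Translational efficiency, the log2 ratio of footprints to input, fell for several oocyte genes in the first step. The ratio rose for some of them in the second. At 12 hpf trailer reads in 26 maternal genes were 61.9% as dense as coding reads, so that rise is not read here as a gain in translation. Between 2 and 5 hpf efficiency fell for cldnd (-6.57), CCNA1 (-4.19) and the RNA-binding protein gene cth1 (-3.13), and 6 of 17 maternal genes fell (median -0.92). Where input or footprints of a stage lie near 0 the ratio is set by the added 1 RPKM, so no change in efficiency from 2 to 5 hpf is given for gastrula or epidermis genes. The largest rises were those of RDH10 (8.53), NSL1, triap1, RIMOC1 and POLR2K, and the largest falls those of ENSDARG00000052717 (-9.01), ENSDARG00000091506 (-7.85) and ENSDARG00000001915 (-7.39). Between 5 and 12 hpf 5 of 11 maternal genes rose (1.69, and 0.66 under scaling), with ENSDARG00000001915 at 10.47, cldnd at 10.32, ccnp at 9.74 and org at 7.77, and their input at 12 hpf lay between 0.698 and 6.96 RPKM. The largest falls of that step included ENSDARG00000096596, ifi27.5, mixl1 and the cold-shock domain gene YBX1 (-3.18). Between 12 and 24 hpf the largest rises included si:dkeyp-20e4.8 (6.31) and copies of the egg-coat gene zp2, whose reads cannot be assigned to 1 copy. In 44 maternal genes the reads at 24 hpf had a median frame index of -0.0046. The rise of zp2, a member of the maternal list, is therefore not read here as a gain in translation. Between 24 and 48 hpf the crystallin gene crybb1l1 (3.29) and the lens fibre membrane gene LIM2 (2.74) rose while RPP38 (-3.49) and he1.3 (-2.82) fell.

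Small ribosomal proteins had a median log2 efficiency of -1.41, -0.83, -0.07, -0.53 and -1.29 at the 5 stages, against 0.08, 0.91, 1.26, 1.33 and 1.24 in long coding ORFs that passed. Histones stood at 4.44 (4 genes) and 4.49 (6 genes) at 2 and 5 hpf and at 2.68 (6 genes) at 48 hpf, in input RNA selected for poly-A. The members with enough input differed between stages. Over 6 genes compared from 2 to 5 hpf the median change was -1.08 (percentile 43.0). Passing trailer ORFs stood at -5.08, -4.65, -3.79, -1.58 and -4.49, and passing leader ORFs at -3.79, -2.31, -0.85, -1.95 and -1.73. Passing was judged over all stages together. An ORF without reads at a stage has a ratio set by its input and the added 1 RPKM. Low values of trailer and leader ORFs are therefore not read here as measured efficiencies. In muscle genes the change between 12 and 24 hpf was 0.81 (percentile 100.0) and turned to -0.07 under scaling and to -0.10 with a pseudocount of 0.1. Respiratory chain genes changed by 0.83 between 5 and 12 hpf, which became -0.17 under scaling. Ribosomal proteins changed by 0.55 and 0.68 over the first steps, within the random range (percentiles 91.7 and 47.3) and against -1.40 and -0.33 under scaling, and by -0.50 and -0.57 over the later steps, below the range and against -1.16 and -0.48. Efficiency of lens genes changed by 1.15 (0.55 under scaling) and of muscle genes by 0.51 (0.60) between 24 and 48 hpf, both above the range. The median input of all 10 measured lens genes at 24 hpf was only 1.99 RPKM. Below the range were epidermis (-1.08) and chaperone (-1.11) genes between 5 and 12 hpf, and membrane (-0.51) and respiratory chain (-0.16) genes between 12 and 24 hpf, and these kept their sign under scaling. Efficiency rose for 995 of 4962 genes and fell for 443 to 5 hpf, rose for 499 of 3779 and fell for 48 to 12 hpf, rose for 66 of 3468 and fell for 6 to 24 hpf, and rose for 8 of 2659 and fell for 13 to 48 hpf. The percent of moved genes that had risen was 69.2, 91.2, 91.7 and 38.1, against 16.3, 29.0, 70.7 and 28.6 after scaling.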

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

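Several tests were chosen after the result was seen. For the 24 hpf column these concerned polyadenylated maternal RNA, early RNA fragments and the 2, 5, 12 and 48 hpf libraries. The muscle and lens tests other than the frame index at 2 hpf were chosen then too. The tests of 24 hpf reads in small ORFs were written after raised trailer efficiency at 24 hpf had been seen for the class. The test for some other library in the 24 hpf column was written before. Its bound, an index not below that of every footprint column, was added after the result was seen. By the rule without that bound the result would have counted for reads of another library.

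Maternal oocyte genes stood out because footprints and input moved in opposite directions between 12 and 24 hpf, by a median of 2.16 (percentile 100.0) in 16 genes and -1.76 in the 3 with enough input, a difference that was not tested. In classes left out of the comparisons, ORFs still passed the stricter threshold. These were 2.13% of ORFs overlapping a coding region from the leader, 1.01% of those overlapping it into the trailer and 24.0% of those sharing its stop codon. An ORF that shares the stop codon lies in the frame of the annotated coding region. Its score can come from reads of the annotated protein, so the share of 24.0% does not speak for separate ORFs.

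The first pattern is footprints of maternal genes at 24 hpf without input: in 44 genes with high input at 2 hpf and almost none later, they were 14.3% of those at 2 hpf in the median, while input was 0.241%. Reads of the 2 hpf library are argued against, since the ratio varied between genes by 3.06 times from the 25th to the 75th percentile. The frame index was also -0.0046 at 24 hpf against 0.534 at 2 hpf. The test of polyadenylated maternal RNA cannot decide, since the genes were chosen for input below 1 RPKM at 24 and 48 hpf. That choice holds the input ratio low, and the footprint ratio exceeded it 34.4 times even in the 25th percentile gene. Of the other footprint libraries, that of 12 hpf is argued against by a 24 hpf level 3.10 times its own in the 25th percentile gene, although the index of these genes was near 0 at 12 hpf already (0.0219), and that of 48 hpf by 21.1 times, while for 5 hpf this level was 0.933 times (2.92 in the median), and its reads are argued against by a frame index of 0.684 in 30 of these genes, from which 24 hpf differed by -0.690 (95% bootstrap interval -0.729 to -0.630). RNA fragments of early embryos that are not footprints remain open, as trailer reads were 0.707 as dense as coding reads in the median of the 26 genes with a long enough trailer at 24 hpf, and so do unphased reads of a library outside the series, as the index lay below that of other genes by a difference of -0.420 (interval -0.426 to -0.410), which well-phased footprints of any library would not give. Maternal RNA with short poly-A tails, which the selected input would miss, is a biological possibility that was not tested and might not lose its frame.

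The second pattern is footprints of muscle and lens genes at 2 hpf, at 1.2% and 1.13% of their 48 hpf level. Fragments that are not footprints are argued against by a median frame index of 0.610 in 19 genes with 13 to 1994 reads (0.609 in the 16 with at least 50), mRNA of these genes at 2 hpf by a footprint ratio 13.6 times the input ratio, and reads of the 24 hpf library by ratios to that stage that differed 9.35 times between muscle and lens genes. Reads of the 48 hpf library in the 2 hpf column remain a candidate explanation, since the ratios to 48 hpf of the 2 lists were within 1.07 times. No biological explanation beyond mRNA at 2 hpf was tested, and the falls of these genes from 2 to 5 hpf rest on this open point. Globin genes, which fell in the same step with a median input of 0.431 RPKM at 2 hpf, were not part of these tests. Nor were epidermis and hatching gland genes, of which 3 fell. Their list had a median input of 0.767 RPKM and median footprints of 29.0 RPKM at 2 hpf.

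The third pattern is small ORFs of leaders and trailers that pass the threshold. At the threshold of 0.0, coding regions of other annotated isoforms are argued against as the main source. The share of passing ORFs in genes with 1 transcript was 0.835 of that in other genes for trailers and 0.946 for leaders. Isoforms missing from the annotation, and ORFs that pass the stricter threshold, were not tested in this way. Reads at 24 hpf that are not footprints remain open for trailers, whose passing ORFs took a median of 60.5% of their reads from 24 hpf (quartiles 0 and 100%, pooled 49.5%) against 21.4% of all coding reads. As the main source they are argued against for leaders, with a median of 0.0% (quartiles 0 and 24.0%), which few reads per ORF favour, 8.77% in ORFs with at least 10 reads, and a pooled 21.7%, near the coding share. Translation of leader ORFs could therefore be a biological source, as a hypothesis, and was not tested beyond frame and coverage.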

How the results depend on the processing

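The alternatives that merged identical values from other read numbers, used a score of at least 6, genes with 1 transcript, the density filter with the threshold unchanged, each stage alone, 24 hpf alone with the threshold unchanged, 12 to 48 hpf without 24 hpf, or an input minimum of 1 RPKM were chosen after seeing the data; the others were planned. Over 64 compared values, 207 outcomes under those planned and 283 under those added kept their direction and side of the threshold, or stayed within 1.5 times for counts. Of the others, 71 planned and 62 added counts left that range, 23 and 8 differences reversed, 8 and 17 passed the threshold only then, and 7 and 6 no longer passed it. Of 155 list medians 35 changed sign under the scaling to an equal median, 4 of them outside the central 95% of random lists, and of 157 under the pseudocount of 0.1, 2 and 1 did. Small ORFs of leaders passed more often than those of trailers except under no coverage minimum and under the density filter with a recomputed threshold. No paired analysis was possible because the table pools the libraries of a stage, so the replicates at 5 hpf cannot be told apart. The planned results on conservation and on column against sucrose at 5 hpf were not run, with all their alternatives, since the table holds neither. Depth limits ORFs with few reads, and 50.6% of coding ORFs at 2 hpf had fewer than 10. Differences below are in percentage points of ORFs that pass, first class minus second, and except where stated the cause was not tested.

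With only the longest ORF per gene and class, passing ORFs numbered 1684 in leaders, 223 in trailers, 231 in non-coding genes, 38 in set A and 13 in set B, which follows from the fewer ORFs. Set A minus trailer was 5.25 (past the threshold), set B minus trailer -0.312 (no longer past it), and non-coding gene minus set A -2.0, reversed. With ORFs at or above the median density of small coding ORFs, which raises the recomputed threshold to 10.28, 4982 long coding, 132 small coding, 9 leader, 9 trailer, 24 non-coding, 11 set A and 1 set B ORFs passed. Reversed with both the filter and the threshold changed were small minus long coding (-30.5), leader minus trailer (-0.284), non-coding (-2.75), set A (-6.22) and set B (-1.71), set B minus trailer (1.43) and non-coding minus set A (-3.47). Set A minus trailer (5.94) passed, and non-coding minus set B (1.04) and set A minus set B (4.51) did not. With the density filter and the threshold unchanged, 5235 long coding, 615 leader, 254 trailer, 255 non-coding, 48 set A and 12 set B ORFs passed. Reversed were small minus long coding (-3.65), set A minus trailer (-2.88) and set A minus set B (-0.41), and no longer past the threshold were non-coding minus trailer (5.00), set B minus trailer (-2.47) and non-coding minus set A (7.88) and set B (7.47).

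At a small limit of 50 codons 9 small coding ORFs passed, small minus long coding was -5.89 and set A minus trailer -0.0747, both reversed, and the median score difference of -1.74 was no longer past the threshold. With at least 20 codons 747 leader, 510 trailer, 421 non-coding, 102 set A and 43 set B ORFs passed; small minus long coding (5.01) and set A minus trailer (1.01) were then past the threshold and set B minus trailer (-0.0127) was not. With the threshold at the 25th percentile 435 leader, 77 trailer, 228 non-coding, 49 set A and 11 set B ORFs passed, set A minus trailer (0.223) was past it and set B minus trailer (0.0298) reversed. With a coverage minimum of 50%, 3801 long coding, 172 small coding, 939 leader, 243 trailer, 242 non-coding, 45 set A and 22 set B ORFs passed; small minus long coding (22.8) and set A minus trailer (0.128) were past the threshold and set B minus trailer (0.0201) reversed. With no coverage minimum ORFs without reads pass at a score of 0.0, which by construction gave 19272 long coding, 16860 leader, 207845 trailer, 22272 non-coding, 17831 set A and 16546 set B ORFs. Then small minus long coding (-3.45), small coding minus set B (-2.0), leader minus trailer (-7.97), non-coding (-4.28), set A (-9.07) and set B (-11.9), non-coding minus trailer (-3.69), set A (-4.79) and set B (-7.66), set B minus trailer (3.97) and set A minus set B (-2.87) reversed. Set A minus trailer (1.1) was past the threshold, and small coding minus trailer (1.97) and set A (0.874) were not.

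Merging identical values from 3 reads gave 1808 trailer and 87 set B ORFs. Set A minus trailer was past the threshold from 3 reads (0.156), 10 reads (0.200) and 100 reads (0.191), and small minus long coding from 50 (4.86) and 100 reads (4.87). A score of at least 6 left 748 leader, 203 trailer, 312 non-coding, 68 set A and 16 set B ORFs, with set A minus trailer past the threshold (0.266) and set B minus trailer reversed (0.00295). Genes with 1 transcript, which are fewer, gave 5316 long coding, 171 small coding, 1463 leader, 1014 trailer and 620 non-coding ORFs, and set A minus trailer was 0.191, past the threshold.

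At 2 hpf alone 2058 long coding, 93 small coding, 573 leader, 214 trailer, 136 non-coding, 31 set A and 9 set B ORFs passed; at 5 hpf alone 5545, 165, 1088, 434, 446, 76 and 42 in that order; at 24 hpf alone 3037, 163, 728, 1378, 289, 54 and 13. At 12 hpf alone 7233 long coding, 2035 leader, 866 trailer, 543 non-coding, 111 set A and 60 set B ORFs passed, and at 48 hpf alone 2025 leader, 354 trailer, 346 non-coding, 127 set A and 44 set B ORFs. Small minus long coding was past the threshold at 2 (12.3), 5 (12.2), 12 (16.3), 24 (24.4) and 48 hpf (13.9). Set A minus trailer was past it at 2 (0.0674), 5 (0.206), 12 (0.197) and 48 hpf (0.509) and reversed at 24 hpf (-0.329), where the threshold recomputed on that stage was -3.39 against 0.0 at the others. With the threshold of 0.0 at 24 hpf, 3032 long coding, 163 small coding, 713 leader, 1310 trailer, 272 non-coding, 53 set A and 13 set B ORFs passed, small minus long coding was 24.5, past the threshold, and set A minus trailer was still reversed (-0.304). Set B minus trailer was no longer past it at 2 (-0.0427) and 12 hpf (-0.0355) and reversed at 5 (0.0517) and 48 hpf (0.0989).

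With the median coding ORF equal in every stage, footprints fell for 3848 genes from 2 to 5 hpf, rose for 421 and fell for 2006 from 5 to 12 hpf, rose for 254 from 12 to 24 hpf and fell for 139 from 24 to 48 hpf. Input rose for 865 and fell for 703 in the first step, rose for 438 in the second and fell for 107 in the third. Efficiency rose for 333 and fell for 1705, rose for 290 and fell for 710, rose for 29 and fell for 12 in the first 3 steps, and rose for 4 in the last. Among medians outside the random range, those that reversed were for footprints of the respiratory chain list from 12 to 24 hpf (-0.12) and of the somite list from 24 to 48 hpf (0.46) and for efficiency of the respiratory chain list from 5 to 12 hpf (-0.17) and of the muscle list from 12 to 24 hpf (-0.0721). With no floor more genes enter, and footprints rose for 2090 from 5 to 12 hpf, rose for 958 and fell for 360 from 12 to 24 hpf, and rose for 572 and fell for 419 from 24 to 48 hpf. Input then rose for 1052 in the second step and 251 in the third and fell for 48 in the last, and efficiency rose for 2894, 1507, 519 and 191 and fell for 840, 207, 80 and 283. From 12 to 48 hpf without 24 hpf footprints rose for 959 and fell for 703, against 562 and 227 or 332 and 270 in the separate steps. With input of at least 1 RPKM, 179 genes fell from 24 to 48 hpf. With a pseudocount of 0.1 efficiency fell for 79 genes from 5 to 12 hpf and 10 from 12 to 24 hpf, rose for 18 from 24 to 48 hpf, and the muscle median from 12 to 24 hpf reversed (-0.10).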

Other observations

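The test on selenoprotein genes was chosen after the result was seen.

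Outside the compared classes, several ORFs with high scores overlapped annotated coding regions. In ENSDARG00000093817 an ORF of 76 codons starting at nt 248 scored 16.44 over 64869 reads, while the annotated ORF, which starts at nt 267 in another frame, scored -15.98. Leader ORFs running into the coding region included those of the creatine synthesis gene GATM (17 codons, 12.16), the selenoprotein gene selenoh (74 codons, 11.84), the stress-response factor gene atf4b (59 codons, 10.74), HS6ST2 (86 codons, 10.18) and RNF10 (72 codons, 10.08). ORFs running from the coding region into the trailer included those of rps20 (8 codons, 14.10), EIF2S3B (4 codons, 12.09) and tbx16 (27 codons, 2247 reads). The ORFs of rps20 and EIF2S3B are shorter than a footprint of 28 to 29 nt, so their scores say little about phasing. ORFs that share the annotated stop included those of si:ch211-152c2.3 (85 codons, 13.59), the chaperone gene PTGES3 (33 codons, 12.93) and atp5mf, a subunit of ATP synthase (76 codons, 12.85). Such ORFs lie in the annotated frame, so their scores can come from reads of the annotated protein.

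ORFs inside coding regions had a median frame index of -0.641 where they had at least 10 reads, and the highest scores among them were those of apoeb (4 codons, 12.24), si:ch211-235f12.2 (17 codons, 11.67), H2AZ2 (3 codons, 11.09) and the mitochondrially encoded MT-CO3 (88 codons, 11.01), the last with an index of 0.0711. The ORFs of apoeb and H2AZ2 are shorter than a footprint, so their scores say little about phasing.

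Genes of selenoproteins, in which a UGA codon is read as selenocysteine, appeared repeatedly among leader and internal ORFs with high scores. Of 25 selenoprotein genes 10 had a leader, leader overlapping or internal ORF with a score of at least 6, against 859 of 18862 other genes, but 5 of them had prompted the test. Without the genes named for a high score, in both groups, the counts were 5 of 20 against 840 of 18825 (Fisher's exact test, odds ratio 7.14, p = 0.00158). The ORFs were those of gpx4a (12.12), selenoh (11.84), SEPHS2 (11.08), GPX4 (10.93), selenop (10.75), selenou1a (9.67), selenop2 (9.32), gpx1a (9.28), SELENOM (7.15) and gpx1b (6.54). A candidate explanation is that the ORF ends at such a UGA and that its reads belong to the selenoprotein itself, so these leader ORFs may be parts of annotated proteins. By the deposited positions all 10 ORFs lie in the frame of the annotated coding region. Those of selenop, selenou1a and selenop2 start where it starts, at nt 223, 141 and 109. The sequences were not used here, so whether each ORF ends at a UGA was not looked at.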
